A study of Mus musculus with 8 samples.

How the data were processed

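RNA was measured in epididymal fat of 4 wild-type and 4 Atg3 knockout male mice. Per the labels' protocols, polyadenylated RNA was purified with oligo(dT) beads, strand-specific TruSeq libraries were made and pooled, and single reads of 50 cycles were sequenced on an Illumina HiSeq instrument. The submitters' processing notes name Novoalign 2.8.1, Picard and the genome build mm10, with no role or order given; the counting program and the annotation are not given in the sources used here. The authors deposited 1 table for all libraries, which per the file headers holds a count of reads and an FPKM value, scaled to gene length and library total, for each gene and library, with the exonic length, coordinates and names of the gene. The counts are whole numbers with totals that differ between libraries, from 10986375 to 21688464, so they were taken as raw counts that the authors had not normalised. The deposited FPKM values were used only to check the file: each of the 158499 values above 0 equals the count divided by the exonic length in kilobases and by the library's total count, on the FPKM scale, within 0.1%.

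Groups and replicate numbers come from the sample titles, and column names match those titles. No library pair of a genotype agreed within sampling noise (the lowest chi-square per gene was 18.2), so all 8 were kept as separate samples. The labels name 4 mice per genotype. Gene symbols and coordinates are those of the file, in build mm10. For 3641 genes the file gives no name, and 25 names had been turned into dates; 32608 identifiers were found in a table of mouse gene names, but none of the unnamed genes was (0), and these genes entered the tests under their identifiers. Whether the counting used strand is not given in the sources used here, so counts of genes that overlap another gene are uncertain. Besides the genes named as such with the results, other gene models overlap Heph, Gsr and Cd247 on the same strand and Sqstm1, Plin4, Nrg4, Foxo1, Pecam1, Gclm, Gyk, Cd247, Acta1 and Alas2 on the opposite strand.

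Differential expression used R 4.3.3 and edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10, which left 14800 of 37417 genes, library sizes were scaled by TMM, and the quasi-likelihood F test (glmQLFit, glmQLFTest, not robust) compared the genotypes with no covariate. P-values were adjusted by the Benjamini-Hochberg method and called at an adjusted p of 0.05. CPM values are TMM-scaled. The standard error of a log2 fold change was derived from the test. Counting intervals of read ratios are exact binomial intervals at 95% and cover counting error only. Library measures and list scores were compared with two-sided exact permutation tests over the 70 assignments of 8 libraries to 4 and 4, whose smallest p is 0.0286. P-values of edgeR and of the permutation tests measure the spread between these mice. Those of camera, the gene list test described next, compare genes with other genes under a preset correlation. Fisher's exact tests and the window scan count genes, so their p-values do not measure the spread between mice.

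Before the data were examined, 32 gene lists were fixed, covering autophagy, lysosomes, stress responses, adipocyte metabolism, other cell types of fat and possible foreign tissue; 869 of their 871 symbols were found. Each list was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 32 lists. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.0765, against 11 with the preset value; fry called 4 lists for a common direction and 14 for change in either direction. The rule for named genes, also fixed before, took Atg3, then the 12 largest increases and 12 largest decreases among called genes with a mean of at least 1 CPM, no overlap between genotypes and a regular gene name, and up to 4 members with the lowest adjusted p of each list. Some genes that the rule took are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

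Alternatives fixed before the data were examined were RLE, upper quartile and library size scaling, no filter or a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, robust edgeR, the replicate number as a block, and each library left out in turn. A pair of alternatives was added after the data were seen: leaving out knockout libraries 2 and 3, and the mean log2 CPM of 21 duct epithelium markers as a covariate. These markers and the lists of prostate, seminal vesicle, heart, liver and epididymal secretory genes were also written after the libraries had been looked at. All 35 splits of the 8 libraries into 4 and 4 were refitted. The script for the test was checked on simulated counts for 14800 genes with the means and depths of these libraries, in which 200 genes were changed. It recovered 46% of genes changed 1.5-fold, 76% at 2-fold, 72% at 3-fold and 92% at 4-fold (50 genes each), with 7 false calls among 150, and camera called 1 of 1 raised list of 40 genes and 0 of 9 unraised lists. The simulated genes varied independently of each other, with dispersions taken from the fitted trend. The check therefore could not test camera's preset correlation, and real recovery may be lower.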

Results

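Epididymal white fat, the visceral fat pad that lies along the epididymis of male mice, was profiled by RNA sequencing in 4 wild-type mice and 4 Atg3 knockout mice of the C57Bl/6 strain. The knockout mice carried a floxed Atg3 gene and Cre recombinase under the adiponectin promoter, which is active in adipocytes, and per the labels all mice received tamoxifen. The series title places the deletion after development. All mice ate chow. Each of the 8 libraries comes from polyadenylated RNA, and the deposited table gives counts for 37417 genes. Total counts ran from 10986375 (wild-type library 1) to 21688464 (knockout library 4) and averaged 14154300 in wild-type and 15528600 in knockout libraries. The other totals were 17128811, 13021878 and 15480022 in wild-type libraries 2 to 4 and 12952190, 13459675 and 14014040 in knockout libraries 1 to 3. Levels below are CPM, read counts scaled to library size, given as mean ± SD with n = 4 libraries per genotype, and log2 fold changes (log2FC) are knockout against wild-type with their standard errors (SE).

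The first comparison asked how far the transcript of the deleted gene was lowered. Atg3 encodes the enzyme that joins LC3-family proteins to the lipid phosphatidylethanolamine, a step in building the autophagosome membrane. Its level fell from 50.2 ± 4.34 CPM in wild-type to 30.3 ± 1.84 CPM in knockout fat (SD, n = 4), 1.66-fold lower. The wild-type libraries held 49.1, 44.5, 53.6 and 53.5 CPM, and the knockout libraries held 30.6, 32.2, 30.8 and 27.8 CPM, so each library sat on the side its label gives. The gene (ENSMUSG00000022663) spans 45158785 to 45188538 on the plus strand of chromosome 16 in build mm10. With edgeR's quasi-likelihood test the log2FC was -0.73 (SE 0.086, adjusted p = 0.0168). Fat holds cells without the deletion, counts cover the whole gene, and the labels do not name the deleted exons. The direction held in every setting run, with adjusted p from 2.25e-09 to 0.147. The settings that lost the call included those without wild-type library 1 (adjusted p = 0.0543), wild-type library 4 (0.0705) or knockout library 2 (0.0745). The call was also lost in 2 alternatives chosen after the data were seen. These were the fit without both knockout libraries 2 and 3 (0.0989) and that with duct epithelium markers as a covariate (0.147).

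**Figure D1:**
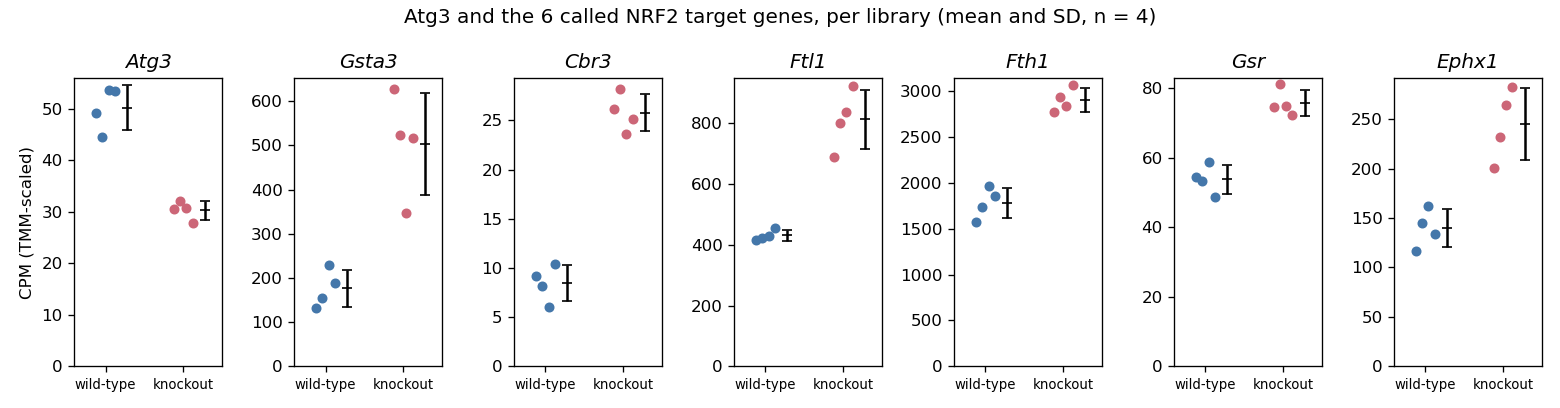
CPM of Atg3 and of the 6 NRF2 target genes that rose, with 1 point per library for the 4 wild-type and the 4 knockout mice and bars for mean and SD; each panel has its own linear axis from 0. The knockout libraries lie between 27.8 and 32.2 CPM for Atg3, all below the wild-type libraries, and above all wild-type libraries for the other genes.

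The second comparison asked which other transcripts differed between the genotypes. Sbsn (suprabasin) rose 4.68-fold, from 38.0 ± 7.76 to 178 ± 58.8 CPM, Slc38a3, a glutamine transporter, rose 8.76-fold from 4.22 ± 2.50 to 36.4 ± 9.69 CPM, and Lama1, a laminin chain, rose 6.30-fold from 1.57 ± 0.667 to 10.0 ± 1.92 CPM (SD, n = 4). Aspa, which cleaves N-acetylaspartate, fell from 38.2 ± 4.80 to 19.4 ± 1.69 CPM, 1.97-fold lower, and Heph, a copper-dependent ferroxidase, fell from 114 ± 10.6 to 63.1 ± 5.82 CPM, 1.80-fold lower. Of 14800 genes tested with edgeR's quasi-likelihood test, 60 passed an adjusted p of 0.05, of which 41 were higher and 19 lower in the knockout. At least 2-fold changes were seen for 25 of them, 20 higher and 5 lower. In all 60 genes the knockout and wild-type libraries did not overlap; among all tested genes this held for 1312, or 8.86%, where chance gives 2.86%. An unadjusted p under 0.05 was reached by 2394 genes, and DESeq2 called 810 and limma-voom 45. The number called was 7 without wild-type library 1, 4 without library 2, 20 without library 3 and 8 without library 4. It was 290 without knockout library 1, 0 without library 2 (edgeR, with 1573 genes at an unadjusted p under 0.05), 23 without library 3 and 44 without library 4; it was 3 without both knockout libraries 2 and 3, an alternative chosen after the data were seen.

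Among the genes with the largest increases, Mmp7 (matrilysin), Camp (cathelicidin) and Uox (urate oxidase) were near the detection floor in wild-type fat. Camp had 2 reads over the 4 wild-type libraries and 202 over the 4 knockout libraries, a depth-scaled ratio of 91.4 with a 95% counting interval from 25 to 760. Its knockout libraries held 1.39, 2.96, 1.02 and 6.20 CPM. Uox had 4 against 314 (ratio 71.1, interval 27.5 to 262), with 1.62, 8.08, 7.97 and 3.22 CPM in the knockout libraries. Mmp7 had 13 wild-type reads, and its knockout libraries held 12.1, 131, 112 and 8.27 CPM, with edgeR's adjusted p at 0.0496. Aass, the first enzyme of lysine breakdown, rose 6.05-fold from 1.06 ± 0.124 CPM, Glp2r, a receptor for glucagon-like peptide 2, rose 5.23-fold from 0.648 ± 0.223 CPM, and Vipr2, a receptor for vasoactive intestinal peptide, rose 4.52-fold from 1.97 ± 0.645 CPM (SD, n = 4). Cbr3, a carbonyl reductase, rose 3.04-fold and Chchd10, a mitochondrial protein, 2.97-fold. Some of these values moved by over 1.5 times between settings, and the fitted values of Mmp7, Camp and Uox depend on the prior count. The log2FC of Camp was 6.04, and 5.31 without knockout library 4, 5.30 with limma-voom and 6.64 with the duct marker covariate. That of Uox was 6.04, and 6.62 without wild-type library 3, 4.96 without knockout libraries 2 and 3 and 4.34 with the covariate; for Mmp7 it was 8.11, and 9.20 without wild-type library 2, 5.44 without knockout libraries 2 and 3 and 4.55 with the covariate. With the covariate the log2FC of Aass fell from 2.60 to 1.64 and that of Chchd10 from 1.57 to 0.96, and none of the calls of these 5 genes was kept. Of 31 named genes called in the main fit, the covariate fit kept 1 call and lost 30, so the loss was not particular to these 5.

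The 12 largest decreases include Atg3, Aspa and Heph. Ifi27l2b and Ifi27l2a, interferon-inducible genes, fell 3.62-fold and 3.60-fold; their gene models overlap on chromosome 12 and are close in sequence, so their reads cannot be assigned with certainty. Sycp3, a synaptonemal complex gene, fell 3.31-fold from 12.4 ± 2.22 to 3.71 ± 1.33 CPM, and Dcst1 fell 2.18-fold from 42.2 ± 9.97 to 19.3 ± 2.37 CPM (SD, n = 4). Arxes1, an X-linked adipocyte gene with a near-identical neighbour that makes its count uncertain, fell 1.97-fold. Smaller decreases were those of Tfpi, the tissue factor pathway inhibitor (1.76-fold), Lgals12, a galectin of adipocyte lipid droplets (422 ± 44.1 to 260 ± 24.7 CPM, 1.62-fold), Fam123b (1.57-fold) and Pfkfb1, a regulator of glycolysis (1.53-fold). Genes on the opposite strand overlap Mmp7, Glp2r, Chchd10, Sycp3, Dcst1, Heph and Pfkfb1, and the counting is not stated to use strand, so these counts are uncertain too; Heph is also overlapped on its own strand. Over the 31 called genes that the naming rule took, with Fth1 and Ephx1 added, each kept its direction in every setting in which it was tested. Of these, 3, 2, 10 and 2 still passed without wild-type libraries 1, 2, 3 and 4, and 31, 0, 14 and 20 without knockout libraries 1, 2, 3 and 4.

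Markers of duct epithelium were measured in all libraries. The 21 genes, a list written after the data were seen that includes keratins 8 and 18, Epcam, Foxj1 and Pax8, summed to 16.6, 26.5, 16.1 and 19.8 CPM in wild-type libraries 1 to 4. They summed to 45.6, 857, 851 and 85.4 CPM in knockout libraries 1 to 4, where Foxj1, a regulator of motile cilia, held 1.15, 100.3, 114 and 4.95 CPM and Lrp2, the endocytic receptor megalin, 8.23, 109, 109 and 9.04 CPM. In knockout library 1 some markers stayed within the wild-type range, such as Lrp2, Rsph1 (0.462 CPM), Tekt1 (0.385 CPM) and Ccdc39 (1.92 CPM). Others stood above it, such as Epcam (2.155 CPM, against up to 0.86 in wild-type) and Krt18 (10.2 CPM, against up to 4.055). The keratins 8 and 18 are also on the mesothelial list, and 14 of the 21 markers passed the filter on low counts. The markers were chosen on these libraries, so their levels are given without a test. The first principal component of the 2000 most variable genes carried 52.5% of their variance and set knockout libraries 2 and 3 (51.6 and 55.5) apart from the other 6 libraries, which lay between -31.9 and -1.57. Mmp7 was spread over the knockout libraries as these markers were: its excess over wild-type in knockout libraries 1 and 4 was 0.0820 of that in libraries 2 and 3, within the range of 0.0271 to 0.225 over 14 tested markers.

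**Figure D2:**
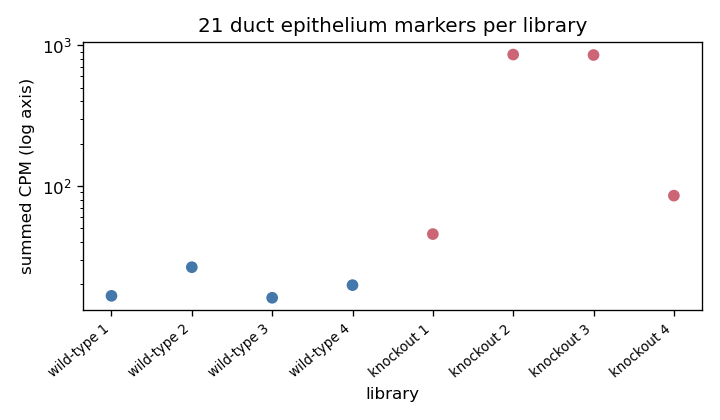
Summed CPM of the 21 duct epithelium markers in each of the 8 libraries, on a log axis, with 1 point per library coloured by genotype. The 4 wild-type libraries sit between 16.1 and 26.5 CPM and the 4 knockout libraries between 45.6 and 857 CPM, with knockout libraries 2 and 3 highest.

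Target genes of NRF2, the transcription factor that activates antioxidant and detoxification genes, stood higher in knockout fat as a group by camera (adjusted p = 3.45e-17 with a preset correlation), a call lost with an estimated correlation (adjusted p = 0.0765). Of 38 tested members 6 rose, 0 fell and 32 did not pass over all genes; 36 had positive log2FC, with a median of 0.35 (1.27-fold) and quartiles of 0.26 and 0.61. Gsta3, a glutathione S-transferase on chromosome 1 (21240589 to 21265361, mm10), rose from 176 ± 42.0 to 504 ± 116 CPM (log2FC 1.51, SE 0.21, edgeR adjusted p = 0.0281). Cbr3, on chromosome 16 (93683215 to 93690990), rose from 8.46 ± 1.84 to 25.8 ± 1.90 CPM (log2FC 1.60, SE 0.16, adjusted p = 0.0168). Ftl1, the ferritin light chain on chromosome 7 (45457944 to 45459884), rose from 431 ± 17.0 to 813 ± 96.2 CPM (log2FC 0.92, SE 0.11, adjusted p = 0.0168), and Gsr, glutathione reductase, from 53.9 ± 4.15 to 75.8 ± 3.79 CPM (log2FC 0.49, adjusted p = 0.0378). Fth1, the ferritin heavy chain (log2FC 0.70, adjusted p = 0.0455), and Ephx1, microsomal epoxide hydrolase (log2FC 0.81, adjusted p = 0.0496), complete the 6. The names of Fth1, Ephx1 and the next 3 genes were chosen after their values were seen. Gclm (log2FC 0.41, adjusted p = 0.0944), Hmox1 (log2FC 0.34, adjusted p = 0.294) and Nqo1 (log2FC 0.27, adjusted p = 0.480) did not pass. Adjusted over the list alone, 20 members passed, all higher. Ferritin and glutathione S-transferase genes have close copies in the genome, and the small RNA gene AC151602.1, also among the 60, lies inside Ftl1, so these counts are uncertain.

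Camera, with a preset correlation of 0.01, set each list against all other genes and was adjusted over 32 lists. For the NRF2 list the adjusted p over the alternatives ran from 2.68e-19 to the 0.0765 of the estimated correlation; fry, which tests whether the genes move one way, gave 0.00273. The mean log2 CPM of the list was 6.14 ± 0.0906 in wild-type and 6.59 ± 0.0929 in knockout libraries (SD, n = 4), without overlap (two-sided exact permutation p = 0.0286, 0.229 after adjustment over 32 lists). The sum of the duct epithelium markers was higher in the same 4 libraries, mainly in libraries 2 and 3. It was 45.6, 857, 851 and 85.4 CPM, against 16.1 to 26.5 in wild-type. The mitochondrial share of counts was higher too, 5.03 to 6.08% against 3.05 to 4.93%. Without knockout libraries 2 and 3 the list had a median log2FC of 0.46, camera's adjusted p was 3.50e-18, 0 members passed over all genes (edgeR, with 1294 genes at an unadjusted p under 0.05) and 16 passed adjusted over the list alone. The knockout libraries kept in that fit, 1 and 4, held 62.8 and 106 CPM of liver genes, against 13.6 to 30.9 CPM in the other 6 libraries, and library 1 held 221 CPM of prostate genes. Members called over all genes numbered 1, 0, 3 and 1 without wild-type libraries 1 to 4, 6, 0, 3 and 2 without knockout libraries 1 to 4, and 16 with DESeq2.

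Aldehyde-metabolising genes and the other antioxidant genes also ranked higher by camera, calls that were lost with an estimated correlation (adjusted p = 0.406 and 0.800). Among 19 tested aldehyde-metabolising genes 1 rose over all genes, Cbr3, which is shared with the NRF2 list, and 4 passed adjusted over the list alone, all higher; the median log2FC was 0.19. Cbr1, another carbonyl reductase and NRF2 list member, had a log2FC of 0.38 (edgeR adjusted p = 0.0908), Aldh1a1, a retinaldehyde dehydrogenase, 0.41 (adjusted p = 0.148), and Aldh3b1 0.51 (adjusted p = 0.166). For the aldehyde list camera gave an adjusted p of 3.45e-04 (alternatives from 2.96e-05 to 0.406), and its mean log2 CPM was 5.94 ± 0.129 in wild-type and 6.22 ± 0.0448 in knockout libraries (SD, n = 4), without overlap (two-sided exact permutation p = 0.0286, 0.229 adjusted over 32 lists). None of the 23 other antioxidant genes passed over all genes with edgeR (0, against 2394 tested genes at an unadjusted p under 0.05), and 2 passed adjusted over the list alone, both higher. Cat, catalase, had 877 ± 140 CPM in wild-type and 1365 ± 141 CPM in knockout fat (log2FC 0.64, adjusted p = 0.101), and Gpx4, which reduces lipid peroxides, had a log2FC of 0.49 (adjusted p = 0.119). The median over these genes was 0.16, with camera's adjusted p at 0.00222 (alternatives from 6.59e-05 to 0.800) and 0.0844 without wild-type library 1. Duct marker levels, 45.6 to 857 CPM, and the mitochondrial share, 5.03 to 6.08%, were higher in the same knockout libraries.

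Adipocyte genes ranked lower in the knockout as a group by camera, a call lost with an estimated correlation (adjusted p = 0.592), and no single member passed. Of 30 tested genes of adipocyte identity and adipokines, 27 had negative log2FC, with a median of -0.30 (1.23-fold lower); 0 passed over all genes (edgeR, with 2394 tested genes at an unadjusted p under 0.05) and 9 passed adjusted over the list alone, all lower. Plin4, a lipid droplet coat protein, had 4735 ± 868 CPM in wild-type and 2570 ± 263 CPM in knockout fat (log2FC -0.88, SE 0.16, adjusted p = 0.0630). Slc2a4, the insulin-regulated glucose transporter, had a log2FC of -0.84 (adjusted p = 0.140), Acsl1, a long-chain acyl-CoA synthetase, -0.72 (adjusted p = 0.125), and Nrg4, a secreted factor, -0.71 (adjusted p = 0.110). Against all other genes camera gave the adipocyte list an adjusted p of 2.03e-07 (alternatives from 6.85e-10 to 0.592). Mean log2 CPM was 10.1 ± 0.215 in wild-type and 9.72 ± 0.170 in knockout libraries (SD, n = 4; two-sided exact permutation p = 0.0571, 0.261 adjusted over 32 lists). Duct marker levels were 45.6, 857, 851 and 85.4 CPM and the mitochondrial share 5.03 to 6.08% in these knockout libraries; without libraries 2 and 3 the median log2FC was -0.18 (camera's adjusted p = 0.00190), and with the duct markers as a covariate it was -0.14 and the call was lost (adjusted p = 0.0892).

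Lipolysis and insulin signalling lists, which share some members with the adipocyte list, ranked lower as well by camera, calls lost with an estimated correlation (adjusted p = 0.298 and 0.0765). Of 17 tested lipolysis genes 15 had negative log2FC, with a median of -0.27, and 3 passed adjusted over the list alone, all lower. G0s2, an inhibitor of adipose triglyceride lipase, had 258 ± 45.8 CPM in wild-type and 133 ± 23.0 CPM in knockout fat (log2FC -0.96, edgeR adjusted p = 0.0524, and 0.0458 and 0.0482 without knockout libraries 1 and 4), its co-activator Abhd5 a log2FC of -0.34 (adjusted p = 0.137) and Adrb3, the adipocyte beta-adrenergic receptor, -0.41 (adjusted p = 0.162). For lipolysis camera's adjusted p was 1.30e-04 (alternatives from 3.78e-06 to 0.298); with the duct marker covariate it was 0.0520 and the median log2FC -0.14. Among 24 insulin signalling and glucose uptake genes the median log2FC was -0.22, and 6 passed adjusted over the list alone, all lower. Foxo1 had a log2FC of -0.53 (adjusted p = 0.131) and Tbc1d4, an Akt substrate that controls glucose transporter traffic, -0.51 (adjusted p = 0.121). For insulin signalling camera's adjusted p was 4.55e-04 (alternatives from 2.03e-04 to 0.0765), and with the covariate it was 0.0289 and the median -0.14. The list's mean log2 CPM lay below the wild-type range in all 4 knockout libraries (6.51 ± 0.0560 and 6.31 ± 0.0374, SD, n = 4; two-sided exact permutation p = 0.0286, 0.229 adjusted over 32 lists). No member of either list passed over all genes with edgeR (0 in each). These 4 knockout libraries also held the higher duct marker levels, 45.6 to 857 CPM, and mitochondrial shares, 5.03 to 6.08%.

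Cholesterol synthesis genes ranked higher by camera, a call lost with an estimated correlation (adjusted p = 0.816), and fatty acid synthesis genes went both ways. Cyp51, the lanosterol demethylase, rose from 23.6 ± 1.43 to 39.6 ± 5.32 CPM (SD, n = 4; log2FC 0.74, SE 0.11, edgeR adjusted p = 0.0286) and was the only 1 of 20 tested cholesterol synthesis genes to pass over all genes. Sqle, squalene epoxidase, had a log2FC of 0.76 (adjusted p = 0.0630, and 0.0316 without knockout library 1), and 4 members passed adjusted over the list alone, all higher. The list's median log2FC was 0.20, with camera's adjusted p at 0.00873 (alternatives from 3.20e-04 to 0.816) and 0.188 without knockout library 4; the median was 0.36 without knockout libraries 2 and 3 and 0.41 with the duct marker covariate. Among 28 lipogenesis genes 14 had positive and 14 negative log2FC. Fads1, a fatty acid desaturase, rose from 89.2 ± 10.9 to 144 ± 16.1 CPM (log2FC 0.70, adjusted p = 0.0486), and Mlxipl, which encodes the carbohydrate response factor ChREBP, had a log2FC of -0.67 (adjusted p = 0.0907). The lipogenesis list did not pass with camera (adjusted p = 0.882). Its median log2FC was 0.06, while camera ranked it lower, and fry's test for change in either direction gave an adjusted p of 0.00422. Duct marker levels were 45.6 to 857 CPM in these knockout libraries, against 16.1 to 26.5 in wild-type, and mitochondrial shares 5.03 to 6.08% against 3.05 to 4.93%.

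**Figure D3:**
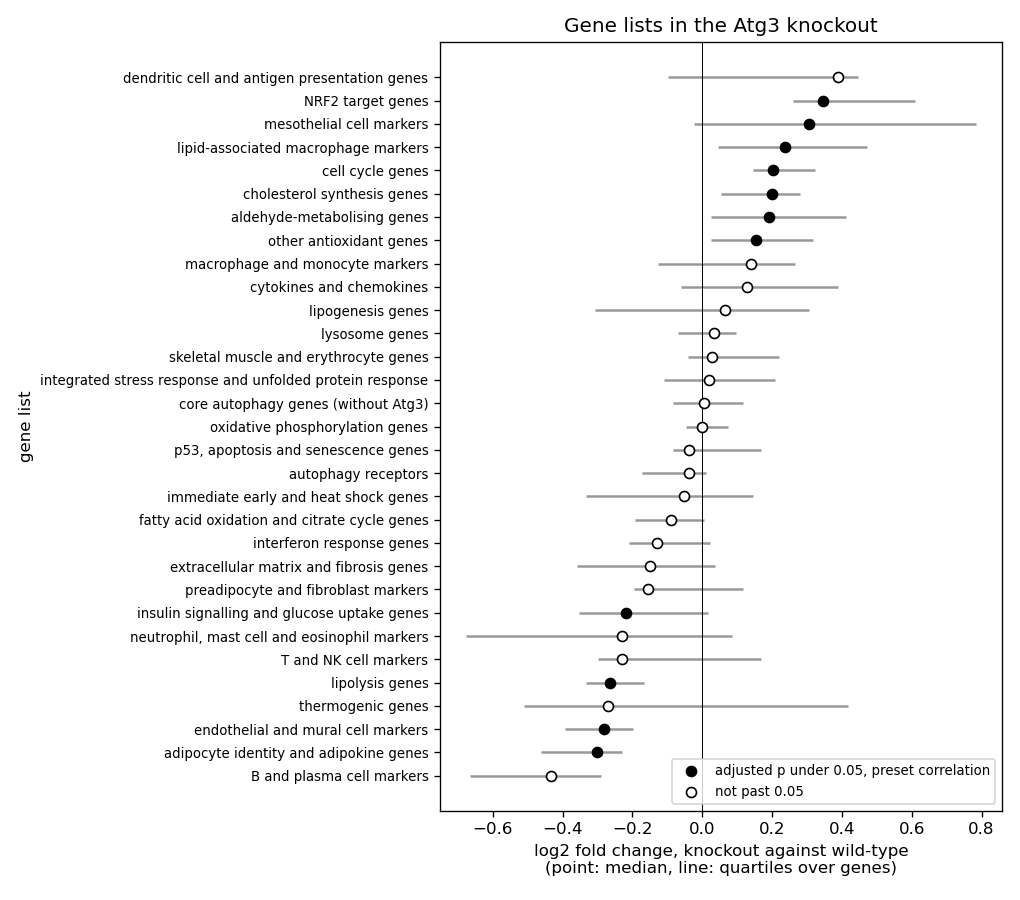
Median log2FC (points) and quartiles (lines) over the tested members of 31 gene lists, knockout against wild-type, with filled points for lists past an adjusted p of 0.05 by camera with a preset correlation. NRF2 target genes lie at 0.35 and adipocyte genes at -0.30; 11 of all 32 lists passed, and 0 with an estimated correlation, and the epididymis and germ cell list, with 1 tested member, is not drawn.

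Core autophagy genes other than Atg3 did not pass the test as a group. Of 34 tested, 0 passed over all genes (edgeR) or adjusted over the list alone, and the median log2FC was 0.0061 (camera's adjusted p = 0.681). Among 13 autophagy receptors Sqstm1, which encodes the cargo receptor p62, had 405 ± 43.9 CPM in wild-type and 514 ± 24.0 CPM in knockout fat (SD, n = 4; log2FC 0.34, adjusted p = 0.159), and Bnip3, a mitophagy receptor, had a log2FC of -0.36 (adjusted p = 0.145). Adjusted over the list alone, 1 receptor gene was higher and 1 lower, and the list did not pass with camera (adjusted p = 0.552). Fry's test for change in either direction gave the receptors an adjusted p of 0.00330. None of the 37 lysosome genes passed over the list alone (0 by edgeR), with a median log2FC of 0.03 (camera's adjusted p = 0.681). Camera's adjusted p was 0.446 for 38 genes of the integrated stress and unfolded protein responses (median log2FC 0.02), whose mean log2 CPM was 5.50 ± 0.0398 in wild-type and 5.60 ± 0.0431 in knockout libraries (SD, n = 4), without overlap (two-sided exact permutation p = 0.0286, 0.229 adjusted over 32 lists). Fry's test for change in either direction gave this list an adjusted p of 0.0318. Camera's adjusted p was 0.808 for 23 p53, apoptosis and senescence genes, whose median of -0.04 and mean of 0.02 differ in sign.

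Vascular markers ranked lower in the knockout by camera, a call lost with an estimated correlation (adjusted p = 0.103). Of 24 tested endothelial and mural cell markers 22 had negative log2FC, with a median of -0.28 (1.21-fold lower); 0 passed over all genes (edgeR) and 7 passed adjusted over the list alone, all lower. Emcn had 62.7 ± 4.23 CPM in wild-type and 46.9 ± 3.39 CPM in knockout fat (log2FC -0.42, adjusted p = 0.0716), Pecam1, the endothelial CD31, 414 ± 18.8 and 317 ± 19.0 CPM (log2FC -0.39, adjusted p = 0.0908), and Tek, an angiopoietin receptor, had a log2FC of -0.42 (adjusted p = 0.137). Vwf, the von Willebrand factor, had 154 ± 74.0 CPM in wild-type and 81.3 ± 6.98 CPM in knockout fat (log2FC -0.93, adjusted p = 0.161). Its wild-type libraries 1 to 4 held 101, 120, 133 and 264 CPM, so the size of this fold leans on wild-type library 4. Camera's adjusted p was 2.59e-05 (alternatives from 2.86e-06 to 0.103); fry gave 0.00895. Duct marker levels were higher in these knockout libraries (45.6 to 857 CPM), as were mitochondrial shares (5.03 to 6.08%), and without libraries 2 and 3 the median log2FC was -0.30 (camera's adjusted p = 9.86e-05).

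Another 3 lists, of cell division, lipid-associated macrophages and mesothelium, ranked higher by camera, calls lost with an estimated correlation (adjusted p = 0.816, 0.800 and 0.816). Cell cycle genes had a median log2FC of 0.20 over 30 tested members, 26 of them positive, with E2f1 at 0.70 (edgeR adjusted p = 0.156) and Cdk1 at 0.66 (adjusted p = 0.177); camera's adjusted p was 0.00222 (alternatives from 8.87e-11 to 0.816), and 0.127 without knockout library 4. Their median was 0.38 without knockout libraries 2 and 3 and 0.45 with the duct marker covariate. Lipid-associated macrophage markers had a median log2FC of 0.24 over 15 members, with Dcstamp at 1.36 (adjusted p = 0.127) and Lgals3, galectin-3, at 0.49 (adjusted p = 0.190), and 1 member passed adjusted over the list alone. With the covariate their median was 0.36. Camera's adjusted p was 0.0258 (alternatives from 0.00107 to 0.800); it was 0.149 and 0.0817 without wild-type libraries 3 and 4, and 0.133 and 0.0640 without knockout libraries 1 and 4. Mesothelial markers had a median log2FC of 0.31 over 17 members, and Krt18 (log2FC 3.57, adjusted p = 0.0908) and Krt8 (log2FC 3.99, adjusted p = 0.107), keratins that are also in the duct epithelium list, passed adjusted over the list alone; over all genes Krt18 passed without knockout library 1 (0.0413) or 4 (0.0488) and Krt8 without library 1 (0.0346). Without knockout libraries 2 and 3 the log2FC was 1.66 for Krt18 and 1.44 for Krt8, with the covariate 1.02 and 0.45, and with limma-voom 2.94 and 3.09. Camera's adjusted p for this list was 0.0244 (alternatives from 3.75e-04 to 0.888); it was 0.558 without wild-type library 3, 0.416 without knockout library 3, 0.528 without knockout libraries 2 and 3 (median log2FC 0.06) and 0.888 with the covariate (median -0.28). None of the 3 lists had a member past the test over all genes with edgeR (0 in each), and duct marker levels were 45.6 to 857 CPM and mitochondrial shares 5.03 to 6.08% in the knockout libraries.

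Other cell types and pathways did not pass with camera. General macrophage and monocyte markers had a median log2FC of 0.14 (adjusted p = 0.371), dendritic cell and antigen presentation genes 0.39 (adjusted p = 0.0567), cytokines and chemokines 0.13 (adjusted p = 0.103) and interferon response genes -0.13 (adjusted p = 0.368). T and NK cell markers had a median of -0.23 (adjusted p = 0.808), although camera ranked them higher, and B and plasma cell markers one of -0.43 (adjusted p = 0.115). Neutrophil, mast cell and eosinophil markers, the list that holds Camp, had a median of -0.23 and a mean of 0.14 (adjusted p = 0.339). Extracellular matrix genes had a median of -0.15 (adjusted p = 0.126), preadipocyte and fibroblast markers -0.16 (adjusted p = 0.446), and skeletal muscle and erythrocyte genes 0.03 (adjusted p = 0.808). Immediate early and heat shock genes had a median of -0.05 (adjusted p = 0.808), although camera ranked them higher, and the 1 tested member of the epididymis and germ cell list had a log2FC of 1.41 (adjusted p = 0.594). That member, Prm2, had 44 wild-type reads, and held 3.53 CPM in wild-type library 1 and at most 0.246 CPM in the other wild-type libraries. Its knockout libraries held 0, 6.89, 1.57 and 1.105 CPM, so its fold depends on single libraries. Oxidative phosphorylation genes had a median of -0.0018 and a mean of 0.0061 (adjusted p = 0.741), fatty acid oxidation and citrate cycle genes -0.09 (adjusted p = 0.120), and thermogenic genes a median of -0.27 and a mean of 0.26 (adjusted p = 0.741). Fry's test for change in either direction gave adjusted p-values of 0.00610 for the neutrophil, mast cell and eosinophil list and 0.0112 for thermogenic genes. Leaving out 1 library brought some of the lists of this paragraph past 0.05 with camera. Without wild-type library 1 the adjusted p was 0.00137 for fatty acid oxidation, 0.0480 for macrophages, 8.71e-05 for dendritic cells, 0.00402 for T and NK cells, 0.00681 for cytokines, 0.00427 for extracellular matrix and 0.00340 for immediate early genes. Fatty acid oxidation and extracellular matrix genes ranked lower there and the others higher, as with all libraries. Wild-type library 1 had the highest mean log2 CPM of all 8 libraries for B and plasma cells (5.08, against 3.48 to 3.92 in the other wild-type libraries). The same held for T and NK cells (3.27 against 1.55 to 2.24) and immediate early genes (5.66 against 4.40 to 4.80). With it left out, camera's adjusted p for B and plasma cells was 0.797. Without wild-type library 2 camera's adjusted p was 0.0178 for fatty acid oxidation and 0.00543 for B and plasma cells, and without library 3 it was 0.0130 for oxidative phosphorylation and 0.0463 for extracellular matrix. Without knockout library 1 it was 0.0353 for fatty acid oxidation, 0.0257 for B and plasma cells and 1.57e-04 for interferon response genes, and without library 2 it was 0.0171 for macrophages and 0.0194 for dendritic cells. Without knockout library 3 it was 0.0425 for cytokines and 0.0291 for extracellular matrix, which also passed without library 4 (0.0123). In separate fits without both knockout libraries 2 and 3 and with the duct markers as a covariate, macrophage markers (adjusted p = 0.0112 and 0.00129), dendritic cell genes (0.0185 and 0.00267) and cytokines (0.0137 and 0.00241) ranked higher, and interferon response genes did with the covariate (0.00393). In all, 11 of the 32 lists passed, 7 higher and 4 lower, and 19 of the 35 ways to split the 8 libraries into 4 and 4 gave 11 lists or more, up to 18.

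Transcripts encoded by the mitochondrial genome took a larger share of counts in the knockout libraries. Their share was 3.71 ± 0.839% in wild-type and 5.64 ± 0.516% in knockout libraries (SD, n = 4), with ranges of 3.05 to 4.93% and 5.03 to 6.08% (two-sided exact permutation p = 0.0286, 0.143 after adjustment over 5 library measures). All 7 tested mitochondrial messenger RNAs had positive log2FC, from 0.09 to 0.74 with a median of 0.53, but 0 passed with edgeR (lowest adjusted p = 0.150). Duct marker levels were higher in the same libraries, 45.6 to 857 CPM against 16.1 to 26.5.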

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

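The tests of duct tissue and of a lower share of adipocytes below were chosen only after the results were seen; the count of splits was planned. Within a genotype, 13 values lay far from the other 3 libraries by Dixon's test (critical value 0.829 for 4 samples), among 194 groups checked, where chance gives about 9.7.

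The total count of knockout library 4 was 21688464, against 12952190 to 14014040 in the other knockout libraries. Wild-type library 3 had 19077 genes detected, against 19517 to 19591 in the other wild-type libraries. In that library Tfpi was at 37.2 CPM (the others at 46.9 to 48.2), Cbr1 at 49.1 CPM (43.9 to 44.3), Acsl1 at 2313 CPM (1426 to 1532) and the mean log2 CPM of the cell cycle list at 2.25 (2.45 to 2.47). Knockout library 4 had Tfpi at 21.6 CPM (the others at 26.6 to 27.6), Aldh3b1 at 29.8 CPM (20.4 to 21.6) and Acsl1 at 1184 CPM (934 to 974). Knockout library 1 had Pfkfb1 at 53.2 CPM (45.8 to 46.2), Nrg4 at 82.3 CPM (63.3 to 63.9) and the interferon response list at a mean log2 CPM of 4.85 (3.86 to 4.00 in the others). In knockout library 3 the fatty acid oxidation and citrate cycle list stood at 7.21 (7.39 to 7.43).

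The numbers of changed genes exceeded what other splits of the libraries gave. The real split called 60 genes, and the highest of the other splits 1; for genes higher in 1 group the values were 41 and 1, for genes lower 19 and 1, and for genes changed at least 2-fold 25 and 1. In each case only 1 of the 35 splits, the real one, gave a result as large, a share under 0.05. A random division of these libraries would thus rarely give such counts. The share is the smallest that 35 splits allow, and the overlapping counts were not adjusted for one another. The counts also depend on single libraries, with 0 genes called without knockout library 2. Of the gene lists, 11 passed in the real split and up to 18 in another, and 19 of 35 splits gave at least 11, so chance cannot be excluded for the number of lists.

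The mean over the NRF2 target genes, of which 6 of 38 passed singly, was higher in each of the 4 knockout libraries than in any wild-type library (two-sided exact permutation p = 0.0286, 0.229 adjusted over 32 lists), and the list's call was lost with an estimated correlation (adjusted p = 0.0765); its mean log2 difference was 0.450 in the real split and 0.329 in the highest of the other splits (1 of 35 as large). Carried-over duct tissue, a candidate source for signals of knockout libraries 2 and 3, would need the rise to shrink without them; the median log2FC was 0.461 without those libraries and 0.345 over all (SE of the list score difference without them 0.0644), which argues against duct tissue as the whole cause. Knockout libraries 1 and 4, on which that value rests, held more liver transcripts (62.8 and 106 CPM) and library 1 prostate transcripts (221 CPM), so other tissue in these 2 libraries stays open. A lower share of adipocytes would need the markers of other cell types to rise; the endothelial and mural score differed by -0.309 on the log2 scale, knockout against wild-type (two-sided exact permutation p = 0.0571), but the genotypes overlapped (knockout up to 7.05, wild-type from 7.04), so this explanation stays open. The Atg3 deletion itself remains an open biological explanation, as does any response of other cells.

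Adipocyte genes ranked lower in the knockout, with a median log2FC of -0.303 (camera's adjusted p = 2.03e-07, a call lost with an estimated correlation, adjusted p = 0.592). With fewer adipocytes, macrophage and endothelial markers would rise alike; the macrophage score minus the endothelial score was higher by 0.353 in the knockout (two-sided exact permutation p = 0.0571), with groups that overlapped (knockout from -1.53, wild-type up to -1.49), so a lower share cannot be told apart from lower expression per adipocyte. Without knockout libraries 2 and 3 the median was -0.184, against a bound of -0.151 for duct tissue and an SE of 0.135, so duct tissue as a cause cannot be excluded either. What keeps both open is the overlap of 4 libraries against 4 and the bulk tissue.

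The genes higher in the knockout were weighed against carried-over duct tissue as a set. In duct epithelium markers the excess over wild-type in knockout libraries 1 and 4 was 0.0271 to 0.225 of that in libraries 2 and 3, and a gene raised by duct tissue alone would share that range. The median over the 41 genes was 0.940 (median absolute deviation 0.341), far above it, which argues against duct tissue as the source of the set; genes with even knockout values pass the test more readily, so this speaks only of the genes called. Just 1 of the 41, Mmp7, lay within the range, and for it duct tissue and the deletion cannot be told apart.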

How the results depend on the processing

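Leaving out knockout libraries 2 and 3 and the duct marker covariate were chosen only after the results were seen; the other settings were planned. RLE, upper quartile and library size scaling, both other filters, limma-voom and robust edgeR gave 45 to 73 changed genes, and the 60 calls kept their sign in each setting (59 of them were tested with the 1 CPM filter). Changed, higher, lower and at least 2-fold changed genes numbered 810, 520, 290 and 336 with DESeq2, which called all 60; the cause was not tested. They numbered 3, 3, 0 and 3 without knockout libraries 2 and 3 (Sbsn, Chrm2 and D3Bwg0562e; 1294 genes at an unadjusted p under 0.05), where fewer samples remain, and 2, 2, 0 and 2 with the covariate (Sbsn and D3Bwg0562e; 1249 at an unadjusted p under 0.05), which takes up part of the genotype difference. Leaving out 1 library gave 0 to 290 changed genes, 0 to 250 higher, 0 to 40 lower and 0 to 222 changed at least 2-fold, the lowest without knockout library 2 (edgeR, 1573 genes at an unadjusted p under 0.05) and the highest without knockout library 1; the cause was not tested. The log2FC of Atg3 was -0.77 without knockout libraries 2 and 3 (adjusted p = 0.0989), -0.79 with the covariate (0.147) and -0.78 to -0.69 with 1 library left out. Depth limits genes near the floor such as Camp, with 2 wild-type reads.

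The labels do not say whether the replicate numbers pair mice. Same-numbered libraries correlated at 0.18, -0.11, -0.25 and 0.06 in their deviations from the group means, and only number 1 correlated best with its own partner. These values gave no sign of pairing, but so few pairs cannot exclude it. With the replicate number as a block, 14 genes changed (4 of them among the 60), 12 higher, 2 lower and 13 at least 2-fold, Atg3 had a log2FC of -0.73 (adjusted p = 0.111), and 13 lists passed, among them dendritic cell (adjusted p = 0.0147) and B and plasma cell (0.0170) lists that had not passed without the block.

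Of the 32 lists, 11 passed; 0 passed with an estimated correlation, where the NRF2 list had an adjusted p of 0.0765, 4 with fry, 13 without knockout libraries 2 and 3, 12 with the covariate and 9 to 17 with 1 library left out. The NRF2 list passed in each other setting run. So did the aldehyde-metabolising, insulin signalling and endothelial and mural lists. The insulin signalling list had the same adjusted p as the NRF2 list with the estimated correlation (0.0765) and with fry (0.00273). Of the results that changed sign, only those of the interferon list (past 0.05 with the covariate) and the mesothelial list (past 0.05 without it) passed on either side of the change. Named genes that changed sign did not pass on either side: with the covariate Fads2 had a log2FC of -0.31, Gyk -0.18, Cd247 0.12, Cdh3 -0.42, Krt19 -0.58, Prm2 -1.65, Acta1 0.45, Alas2 -0.13 and Hsph1 -0.31; without knockout libraries 2 and 3 Krt19 had -0.096, Prm2 -0.52 and Alas2 -0.067; with 1 library left out Il7r ran from -0.41 to 0.0017 and Mylpf from -0.027 to 0.45. The adjusted p-values of lists that changed direction without knockout libraries 2 and 3 were 0.491 for lipogenesis, 0.491 for interferon response and 0.727 for skeletal muscle and erythrocytes. With the covariate they were 0.485 for lipogenesis, 0.551 for fatty acid oxidation, 0.00393 for interferon response (now higher), 0.888 for mesothelial markers (now lower), 0.850 for epididymis and germ cells and 0.943 for immediate early genes. Some lists changed direction with 1 library left out, and none passed in a fit in which it did; over all 8 such fits, with or without a change of direction, their adjusted p-values ran from 0.431 to 0.976 for core autophagy, 0.270 to 0.976 for lysosomes, 0.518 to 0.9997 for p53, 0.283 to 0.987 for lipogenesis, 0.0130 to 0.908 for oxidative phosphorylation, 0.00402 to 0.923 for T and NK cells, 0.00543 to 0.797 for B and plasma cells, 1.57e-04 to 0.966 for interferon response, 0.672 to 0.976 for skeletal muscle and erythrocytes and 0.00340 to 0.987 for immediate early genes. The causes were not tested.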

Other observations

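The lists of foreign tissues and the chromosome 1 test were chosen only after the libraries had been looked at; the test of genes around Atg3 was planned before its result was seen.

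Several libraries held transcripts of other organs. Prostate genes summed to 221 CPM in knockout library 1, with Tgm4 at 146 CPM and Pbsn, probasin, at 67.9 CPM, against 0.0820 to 3.27 CPM in the other 7 libraries. Seminal vesicle genes reached 4.76 CPM in wild-type library 3, from 58 reads, and lay between 0 and 0.131 CPM in the others. Epididymal secretory genes, most of them also on the fixed epididymis and germ cell list, summed to 65.4 CPM in knockout library 3 and to at most 5.0 CPM elsewhere. Liver genes summed to 62.8 and 106 CPM in knockout libraries 1 and 4 and to 13.6 to 30.9 CPM in the other 6 libraries. The heart muscle genes Myh6, Myl2 and Myl3 stood at 5.0, 3.03 and 2.16 CPM in knockout library 4 and at no more than 0.308 CPM each in any other library; the heart list summed to 23.6 CPM there and to 22.7 and 20.3 CPM in knockout libraries 2 and 3, where most of it came from Tnni3 and Tnnt2.

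A hypothesis tested was that DNA from the strain of the floxed allele, carried along with it, changed genes near Atg3. Of 81 tested genes within 10 Mb of Atg3 on chromosome 16, 14 had an unadjusted p under 0.05, against 2380 of 14719 others, an odds ratio of 1.08 (one-sided Fisher's exact p = 0.439). The excess was not larger than chance, and a few such genes may still be affected. Besides Atg3, Lrrc58 was a called gene in this window (log2FC -0.52, edgeR adjusted p = 0.0168), and was named after its values were seen. It held 138 to 141 CPM in wild-type and 93.2 to 102 CPM in knockout libraries. Another gene model overlaps Lrrc58 on the same strand, so its count is uncertain. The test counted genes as a set, so it cannot tell whether carried-along DNA changed Lrrc58.

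Another hypothesis was that 1 wild-type mouse carried a segment of another strain on distal chromosome 1. The region was found by scanning 10 Mb windows of all libraries for genes at which 1 library stood apart from the other 7. In wild-type library 4, 22 of 198 tested genes from 170 Mb on stood apart, an odds ratio of 4.07 against its other genes (one-sided Fisher's exact p = 2.10e-07), and the highest odds ratio of another library was 1.72. Among 2192 tests of the scan, each of 1 window in 1 library, 5 passed an adjusted p of 0.05. The lowest was 170 to 180 Mb in this library (adjusted p = 0.00168), and 80 to 90 Mb of chromosome 1 in the same library followed (adjusted p = 0.00207). The other 3 were 60 to 70 Mb of chromosome 6 in knockout library 4 and in wild-type library 4, and 20 to 30 Mb of chromosome 13 in wild-type library 1. The scan counted genes as independent, so neighbouring genes that vary together for another reason could also give such windows. Wild-type library 4 and knockout library 4, which share the chromosome 6 window, had the lowest immunoglobulin shares of counts. These were 0.300% and 0.344%, against 0.501 to 0.744% in the other libraries. A segment of another strain stays a hypothesis, since it was found and tested on the same libraries and no genotypes were analysed here.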
